A study of Mus musculus with 11 samples.

How the data were processed

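RNA was measured by sequencing in 11 mouse high-grade gliomas, 9 labelled as tumours with prolonged Ezh2 knockdown and 2 as controls without it. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with the Illumina TruSeq RNA kit and sequenced on a HiSeq2000. The deposited file is one table with a whole-number count of reads per Ensembl gene for each tumour, as read from its values. Per the submitters' processing notes, the tools TopHat 1.4.0 and HTSeq and the genome build mm9 were used to make those counts. The roles and settings of these tools, the use of strand in counting and any filter on reads are not given in the sources used here. Without strand, reads of overlapping genes on opposite strands cannot be told apart, and another gene model overlaps 5 of the 24 genes with the largest changes named in the report. Reads of near-identical paralogs may have been split or left out. Gene symbols and coordinates were taken from the table itself, which pairs them with Ensembl identifiers on mm9. The reference annotation at hand is of a later build, so that no coordinate was taken from it.

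The groups and the replicate numbers were taken from the sample titles. Per the series' design text, mice received doxycycline in the drinking water or not, while the labels' treatment field gives the same protocol (2 mg/ml with 1% sucrose) for every tumour. Whether the controls drank doxycycline is thus not settled, and any effect of the drug itself cannot be told apart from that of the hairpin. The labels do not say whether tumours came from separate cell preparations or injections, so that p-values measure only the spread between these samples, which may be technical. Replicates were compared by Pearson's r of log2 CPM, which lay between 0.926 and 0.984 among the knockdown tumours and was 0.964 between the controls. The smallest chi-square per degree of freedom over genes, comparing the counts of replicate pairs, was 12.1, so that no library was a copy of another.

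The table held 27687 genes. Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr on the groups, which kept 16241 genes with 99.9% of the counts, and TMM factors, between 0.919 and 1.077, scaled the libraries. Knockdown was compared with control over all 11 libraries by the quasi-likelihood F-test without covariates (estimateDisp, glmQLFit and glmQLFTest with their defaults), and p was adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The common biological coefficient of variation was 33.9%. The SE of a log2 fold change was taken as its size divided by the square root of F. Group levels are means and SDs of TMM-scaled CPM, and a fold without an SE is 2 to the power of the fitted log2 fold change. A count of 3, used as the floor, corresponded to between 0.161 and 0.268 CPM in a library. For genes with 1 to 3 counts over the controls the ratio of summed counts is given with a 95% exact binomial interval, which covers counting error only.

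For Ezh2, an exact two-sided permutation test was run on log2(CPM + 1) over the 55 splits of the libraries into 9 and 2, for which the smallest p is 0.018. The 44 gene lists had been written from general knowledge of the tissue and treatment before the data were examined. Of 1134 symbols 1098 were found directly, 7 through an alias and 10 through a table of current symbols, and 19 were not matched. The 43 lists with 5 or more tested members were compared with all other genes by camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, two-sided and adjusted over the 43 lists. Of the 13 lists that passed, 0 passed with the correlation estimated from the data, whereas fry, which asks whether genes of a list move on balance one way and does not set them against other genes, called 12 lists. Members were counted as higher or lower at the threshold over all genes tested, and again with p adjusted over the list alone, which the report gives where that count differs. Scores of lists are means of log2(CPM + 1). Relations among the 9 knockdown tumours were tested by enumerating all pairings (exact permutation, two-sided), where the plan had named random resamples for the first family, and adjusted within each family.

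The rule for named genes was also written before the data were examined: Ezh2, then the 12 genes with the largest positive and the 12 with the largest negative log2 fold change among those with an adjusted p under 0.05, an average log2 CPM of at least 2, every knockdown tumour on the same side of both controls, and a symbol that is not a predicted, Rik, pseudogene or antigen receptor segment name. From each list up to 4 members were named, the 2 with the smallest p that rose and the 2 that fell, or the 2 with the smallest p where none passed. All PRC2 subunits, engineered genes and sex-linked markers were to be named as well. A few genes that the rule takes are not reported here.

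The test was tried on counts simulated from the real means and library sizes. Of 86 genes changed by 2-fold it recovered 25 (29.1%), and of 104 changed by 4-fold 64 (61.5%), among 15992 genes tested in the comparison of knockdown with control. Of 91 calls 2 were false. The alternatives were RLE and upper-quartile factors, no filter and a stricter filter on low counts (over 1 CPM in at least 2 libraries and a mean count of 50), DESeq2 1.42.0, limma-voom, robust empirical Bayes, a test against a 1.5-fold change, library sizes without genes that took over 1% of a library, a pseudocount of 0.1, each library left out in turn, and the replicate number as a block over the 4 libraries whose numbers occur in both groups. Chosen after seeing the data were a fit on libraries with over 1.5 CPM of Xist and a fit without knockdown libraries in which a whole chromosome was shifted. Plots were drawn with matplotlib from these values.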

Results

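Messenger RNA was counted per gene in 11 mouse high-grade gliomas. The tumours had grown in the brains of immunodeficient NOD-SCID mice after injection of glioma-initiating cells, which are neural stem cells of the subventricular zone taken from 7-day-old mice and made tumorigenic in culture by Cre recombinase acting on conditional alleles, p53 and Ink4a/Arf among them. The cells carried a short hairpin RNA against Ezh2 that doxycycline switches on. Per the labels, 9 tumours had prolonged Ezh2 knockdown and 2 were controls without knockdown. The libraries held between 11209233 and 18638382 counts over genes, and between 20197 and 21505 genes had at least 1 count. The share of counts on mitochondrially encoded genes was 8.40% ± 3.58 (SD, n = 9) in the knockdown tumours and 4.87% ± 0.823 (SD, n = 2) in the controls, which did not differ beyond the spread (exact two-sided permutation p = 0.22). On the first principal component, which held 37.0% of the variance, both controls lay at 97.2 and 103.6 and the 9 knockdown tumours between -44.4 and -8.96. The comparison describes how the transcriptomes of tumours labelled as prolonged Ezh2 knockdown differed from those of the 2 controls. Any effect of doxycycline itself cannot be told apart from that of the hairpin.

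Ezh2, the histone methyltransferase subunit of Polycomb repressive complex 2 (PRC2), was lower in every knockdown tumour than in either control. Its level was 16.2 ± 8.69 CPM (counts scaled to the library size; SD, n = 9) in the knockdown group and 49.0 ± 5.21 CPM (SD, n = 2) in the controls, so that 33.1% of the control level remained on average. The remaining level ran from 14.8% in knockdown 8, at 7.27 CPM, to 62.1% in knockdown 3, at 30.4 CPM, and knockdown 9 was close to the latter at 30.1 CPM. The log2 fold change of Ezh2 (ENSMUSG00000029687, mm9 chromosome 6, 47480273 to 47545340) was -1.59 ± 0.44 (SE; edgeR quasi-likelihood test, adjusted p = 0.023). In the exact two-sided permutation test over the 55 ways to split the libraries, p was 0.018, the smallest value that these group sizes allow. With only 1 of the controls in the fit the edgeR call was lost, at log2 fold changes of -1.70 without control 1 (adjusted p = 0.11) and -1.48 without control 2 (adjusted p = 0.14), while a test against a 1.5-fold change gave an adjusted p of 0.091.

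**Figure D1:**
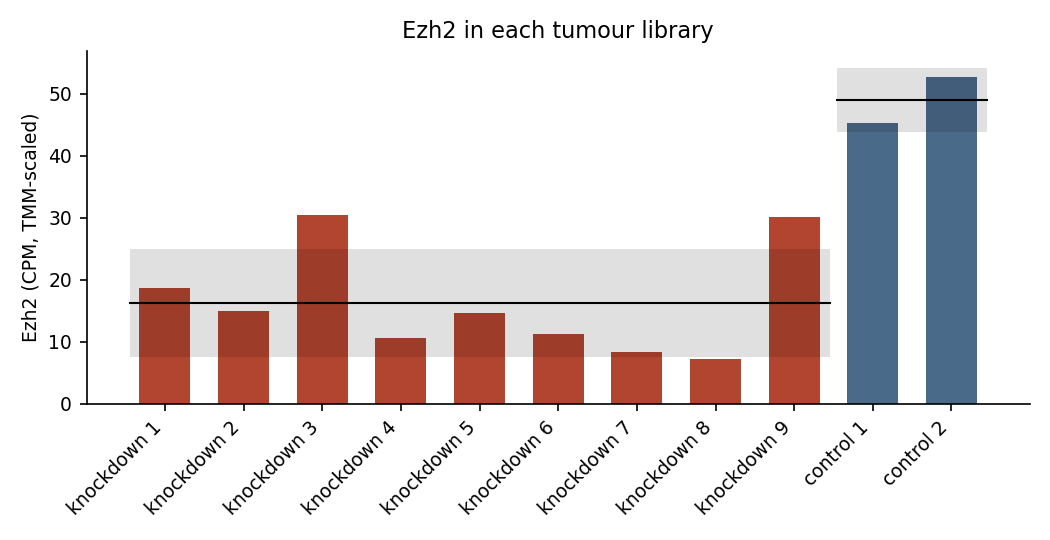
Ezh2 level in CPM, scaled by TMM factors, for each of the 9 knockdown (red) and 2 control (blue) tumour libraries; lines are group means and grey bands 1 SD. The knockdown libraries sit between 7.27 and 30.4 CPM, all below the controls at 45.3 and 52.7 CPM.

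Of the other 10 subunits of PRC2, 4 rose and 6 did not pass the test. Ezh1, the other methyltransferase of the complex, rose 1.73-fold, from 33.5 ± 6.85 to 57.9 ± 6.13 CPM (edgeR, adjusted p = 0.0040). The accessory subunits Mtf2 (log2 fold change 0.79 ± 0.16 SE, adjusted p = 0.0060), Jarid2 (0.96 ± 0.28, adjusted p = 0.028) and Phf19 (1.10 ± 0.34, adjusted p = 0.035) also rose. The core subunits Suz12 (0.13 ± 0.19) and Eed (0.21 ± 0.14), and Aebp2 (-0.09 ± 0.11), Phf1 (-0.03 ± 0.15), Rbbp4 (0.20 ± 0.13) and Rbbp7 (0.32 ± 0.11, adjusted p = 0.060), did not pass the test. In all, 4 of the 11 subunits rose and 1, Ezh2, fell, and 5 rose when p was adjusted over the list alone. As a list the subunits did not pass camera, the test of a list against the other genes (adjusted p = 0.12). Of the 19 measured subunits of PRC1, the partner complex, 3 rose and 1 fell. Rnf2, its catalytic ubiquitin ligase, rose 1.44-fold (adjusted p = 0.0094), Pcgf2 rose 1.51-fold and Pcgf5 fell 2.39-fold (list adjusted p = 0.48). With 1 control left out, 1 PRC2 subunit still rose in either case and Ezh2 no longer passed.

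Across the transcriptome, 3790 of 16241 tested genes (23.3%) differed between knockdown and control tumours (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 1674 higher and 2116 lower in the knockdown. By over 4-fold, 492 were higher and 380 lower. A gene list in which about 23.3% of the members changed does not stand out from all tested genes by its number of calls. In 4412 tested genes (27.2%) the 9 knockdown libraries did not overlap the controls, against 3.64% for a random split. The count rests on the 2 controls together: it was 1290 without control 1 and 1750 without control 2, and 1159 genes passed a test against a 1.5-fold change.

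The most increased genes that passed the rule for naming were close to silent in the controls and included receptors and fetal RNA-binding proteins. Agtr2, the type 2 angiotensin receptor (ENSMUSG00000068122, mm9 chromosome X, 21061670 to 21066290), had the largest log2 fold change, 7.53 ± 2.33 (SE; edgeR, adjusted p = 0.036), but ranged between 1.26 and 155.6 CPM over the knockdown tumours. Asb4, an imprinted gene (ENSMUSG00000042607, mm9 chromosome 6, 5333386 to 5383022), was the most uniform: 37.7 ± 13.8 CPM in the knockdown tumours against 0.241 ± 0.0140 CPM in the controls, a log2 fold change of 7.24 ± 0.72 (adjusted p = 0.00011). The RNA-binding proteins Igf2bp1 and Lin28b, which are normally expressed in fetal tissue, rose by 5.30 ± 1.27 (adjusted p = 0.012) and 5.05 ± 1.09 (adjusted p = 0.0074). Chrm2, a muscarinic acetylcholine receptor (5.25 ± 0.95), Gria4, a glutamate receptor subunit (5.10 ± 1.08), Hkdc1, a hexokinase (5.17 ± 1.03), C1qtnf7 (5.04 ± 0.92) and Prr19 (5.34 ± 1.17) rose as well. Nrk rose by 6.16 ± 1.96, on 2 counts over both controls. From the summed counts, Nrk was 72.2-fold higher (95% exact binomial interval 19.9 to 597.5, counting error only). With 1 control left out, Agtr2, Nrk, Prr19, Igf2bp1, Gria4 and Lin28b no longer passed the test in either case, and Hkdc1 did not pass without control 2 (adjusted p = 0.059), although all stayed higher. These 7 genes did not pass limma-voom either, with adjusted p between 0.064 for Lin28b and 0.34 for Agtr2. Chrm2 and C1qtnf7 passed without control 2 at 4.40 and 4.26.

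The most decreased genes that passed the rule for naming included granule proteins of neutrophils and mast cell proteases. Ngp, neutrophilic granule protein (ENSMUSG00000032484, mm9 chromosome 9, 110322254 to 110325514), fell from 25.3 ± 22.8 to 0.0632 ± 0.0731 CPM, a log2 fold change of -8.49 ± 0.64 (edgeR, adjusted p = 2.7e-05). The neutrophil genes S100a9 (-5.02 ± 0.53) and Ltf, lactoferrin (-4.68 ± 0.57), and the mast cell proteases Mcpt1 (-5.32 ± 0.75) and Mcpt2 (-5.19 ± 0.85), a pair of paralogs between which reads may have been split, fell too. Mmp13, collagenase 3 (mm9 chromosome 9, 7272514 to 7283333), dropped from 875 ± 445 to 19.4 ± 26.3 CPM (-5.49 ± 0.83, adjusted p = 0.0011), and Smoc2, a secreted calcium-binding matrix protein, from 480 ± 211 to 14.7 ± 8.69 CPM (-5.03 ± 0.60, adjusted p = 0.00030). Rgs8 (-6.15 ± 0.60), a regulator of G protein signalling, Klhl1 (-5.65 ± 0.97), Pcdh8 (-4.87 ± 0.66), a protocadherin, and Gpr149 (-5.03 ± 0.93) completed the group. Slc6a11, a GABA transporter, fell by 5.05 on the log2 scale, but its level was 3.23 CPM in control 1 and 130.5 CPM in control 2, and without control 2 the log2 fold change was -0.69 (adjusted p = 0.58). Gpr149 also lost its call without control 2 (adjusted p = 0.080). Rgs8 stood at 201 CPM in control 1 and 15.3 CPM in control 2, and without control 1 its log2 fold change was -3.34 (adjusted p = 0.0053). Without control 1 the values of Ltf, S100a9 and Ngp were -2.99, -4.18 and -7.03, and without control 2 those of Klhl1 and Mmp13 were -4.63 and -4.85, all still past the test.

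Of 52 measured developmental regulators outside the Hox clusters, which PRC2 is known to hold silent in stem cells, 11 rose and 1 fell. The share that changed was close to the 23.3% of all tested genes, so that the list does not stand out by its number of calls. Its median log2 fold change was 0.84 (camera, adjusted p = 0.0097, and adjusted p = 0.59 with an estimated correlation). The T-box repressor Tbx2 rose from 36.3 ± 27.6 to 391 ± 89.5 CPM (log2 fold change 3.43 ± 0.46, adjusted p = 0.00062) and Twist1, a basic helix-loop-helix factor, 7.25-fold (adjusted p = 0.0025), whereas Six3, a forebrain homeobox gene, fell 4.33-fold (adjusted p = 0.0056). The call of this list was lost without control 2 (adjusted p = 0.25) and without the filter on low counts (adjusted p = 0.28). Of 12 measured Hox genes none rose and 1, Hoxb4, fell 4.39-fold to 0.363 ± 0.203 CPM, and no Hox gene passed without control 2. The median of the Hox list was 0.63, while camera placed it in the lower direction (adjusted p = 0.86). At 0 in both controls were 3 of these Hox genes and 1 of the other regulators, and setting them at the bound that 3 counts over the control group allow left both medians at 0.63 and 0.84. Among 26 imprinted genes 6 rose and 2 fell, or 7 and 3 adjusted over the list alone (list adjusted p = 0.11). Besides Asb4, Peg10 rose 4.57-fold to 500 ± 122 CPM, while Grb10 fell 3.41-fold and Mkrn3 fell 2.67-fold. The 24 genes of the pluripotency network went both ways, 7 up and 5 down (6 down adjusted over the list alone; list adjusted p = 0.53). Tet1, a methylcytosine dioxygenase, rose 2.52-fold beside Lin28b, and Gdf3 and Tdgf1 fell 19.2-fold and 4.22-fold. Both were scarce, Gdf3 falling from 2.74 ± 0.287 to 0.142 ± 0.107 CPM and Tdgf1 from 1.82 ± 1.05 to 0.426 ± 0.239 CPM.

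Part of the cell cycle genes rose. Of 38 genes of S phase 14 rose and none fell at the threshold over all genes, and 27 rose and 1 fell adjusted over the list alone, with a median log2 fold change of 0.79 (camera, adjusted p = 1.7e-07; adjusted p = 0.68 with an estimated correlation). Tipin, of the replication fork protection complex, rose 2.60-fold (adjusted p = 0.00030) and Slbp, the histone mRNA stem-loop binding protein, 1.99-fold (adjusted p = 0.0025). Of 44 genes of G2 and M phase 11 rose, 12 adjusted over the list alone, and none fell. At the threshold over all genes this share was close to the 23.3% of all tested genes that changed. The median of the list was 0.79 (camera, adjusted p = 4.0e-07, and adjusted p = 0.79 with an estimated correlation). Cdk1, the mitotic kinase, rose 1.99-fold from 60.8 ± 12.9 CPM (adjusted p = 0.0089) and the condensin subunit Smc4 from 98.4 ± 8.55 to 197 ± 42.5 CPM (adjusted p = 0.012). Of 72 DNA repair genes 17 rose and 3 fell, or 18 and 4 adjusted over the list alone (median 0.43; adjusted p = 0.0011, and adjusted p = 0.83 with an estimated correlation). Fance and Rad51ap1, of the Fanconi and homologous recombination pathways, rose 2.60-fold and 3.16-fold, and the excision repair genes Ercc1 and Ercc4 fell 1.5-fold and 1.44-fold. All 3 lists kept their camera call without either control, but without control 1 only 1 S phase gene, 0 G2 and M phase genes and 1 repair gene passed singly by edgeR, and without control 2 it was 9, 3 and 12. In the 7 libraries with Xist reads, chosen after seeing the data, 30, 29 and 30 genes of these lists rose. Of 27 cyclin-dependent kinase inhibitors and p53 targets 2 rose and 4 fell (list adjusted p = 0.48), close to the 23.3% of all tested genes that changed. Their median was 0.01 against a mean of -0.10, and the median turned to -0.02 under size factors of the RLE method. Fas and the inhibitor Cdkn2c rose 3.32-fold and 2.11-fold, and Zmat3 and Bbc3 fell 2.48-fold and 1.85-fold.

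**Figure D2:**
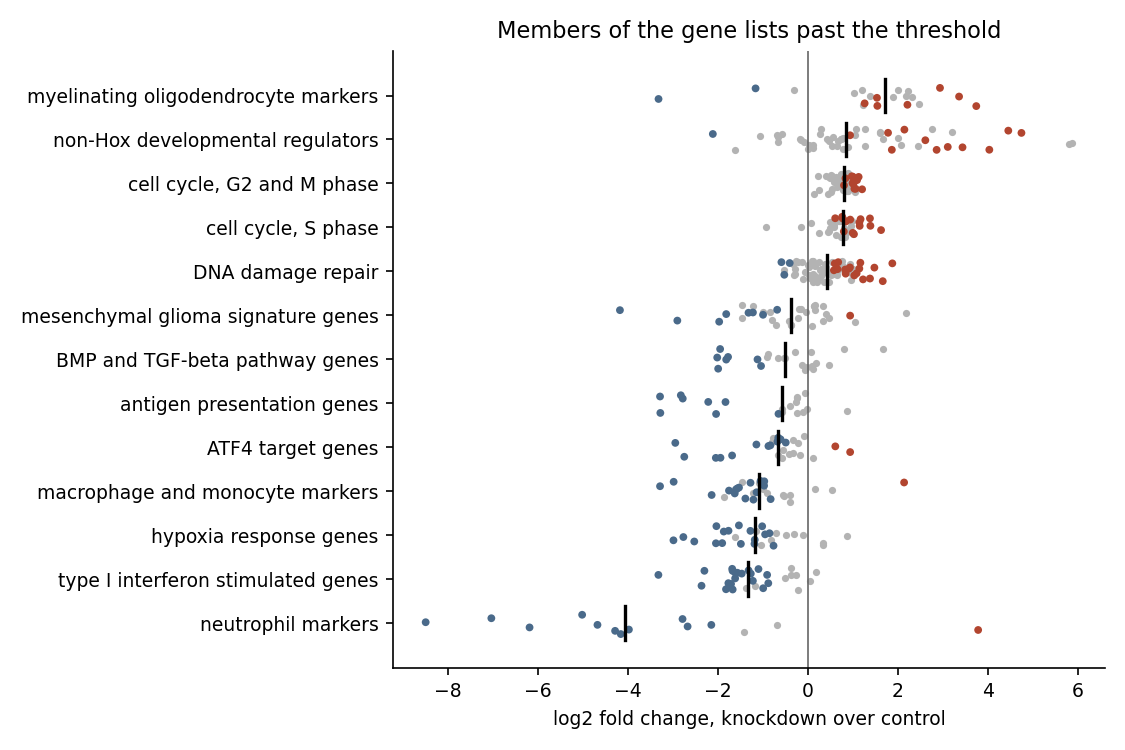
Log2 fold change, knockdown over control, of each measured member of the 13 gene lists that passed camera; red and blue points passed edgeR's test upward and downward, grey points did not, and black bars are list medians. Medians run from -4.07 for neutrophil markers to 1.72 for myelinating oligodendrocyte markers.

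Markers of myeloid cells, interferon-stimulated genes and antigen presentation genes, chiefly those of MHC class II, were lower in the knockdown tumours. Of 14 neutrophil markers 11 fell and 1 rose, with a median log2 fold change of -4.07 (camera, adjusted p = 4.3e-08; adjusted p = 0.13 with an estimated correlation). Mpo, myeloperoxidase, fell by 7.03 ± 0.67 on the log2 scale beside Ngp, while Lcn2, lipocalin 2, which astrocytes and epithelia also make, rose 13.7-fold (adjusted p = 0.020). Of 31 macrophage and monocyte markers 16 fell (20 adjusted over the list alone) and 1, Plac8, rose 4.39-fold (median -1.08; adjusted p = 1.6e-06, and adjusted p = 0.68 with an estimated correlation). The scavenger receptor Msr1 went from 136 ± 56.1 to 45.9 ± 6.59 CPM and Cd74, the invariant chain of MHC class II, from 654 ± 619 to 67.2 ± 38.8 CPM. This list depended on control 2, without which its median was -0.46 and 3 members fell (adjusted p = 0.017). Of 30 genes stimulated by type I interferon 21 fell (23 adjusted over the list alone) and none rose (median -1.34; adjusted p = 8.6e-10, and adjusted p = 0.68 with an estimated correlation), among them the chemokine Cxcl10 (log2 fold change -3.32 ± 0.38, adjusted p = 0.00027) and the ubiquitin-like Isg15 (-1.77 ± 0.25, adjusted p = 0.00076). Without control 1, 14 of the interferon genes fell, and without control 2 it was 6, at medians of -1.58 and -1.12. Of 19 antigen presentation genes 8 fell and none rose (median -0.58; adjusted p = 0.0028, and adjusted p = 0.68 with an estimated correlation), with H2-Eb1, a class II chain, 9.70-fold lower. Among the class I genes of the list Tapbp fell 1.57-fold, whereas H2-K1 (-0.25 ± 0.52), H2-D1 (-0.58 ± 0.48) and B2m (-0.59 ± 0.32) did not pass. That list lost its call without control 2 (0 members, adjusted p = 0.21). Microglia markers showed 6 lower and 1 higher of 17 (7 lower adjusted over the list alone; list adjusted p = 0.16), with Sparc falling 2.62-fold, Selplg 2.69-fold and Slc2a5 rising 6.00-fold, on 7 counts over both controls. Without control 1 the microglia list passed (adjusted p = 0.022). Of 11 markers of lymphocytes and natural killer cells 1, the kinase Lck, rose 3.28-fold and 2, Klrb1c and Cd4, fell 12.7-fold and 6.59-fold (list adjusted p = 0.52). Klrb1c was near the floor in the knockdown, at 0.188 ± 0.128 CPM. Cd4 stood at 4.77 CPM in control 1 and 18.1 CPM in control 2, while knockdown tumours reached 4.91 CPM, so that its fall depends on control 2.

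**Figure D3:**
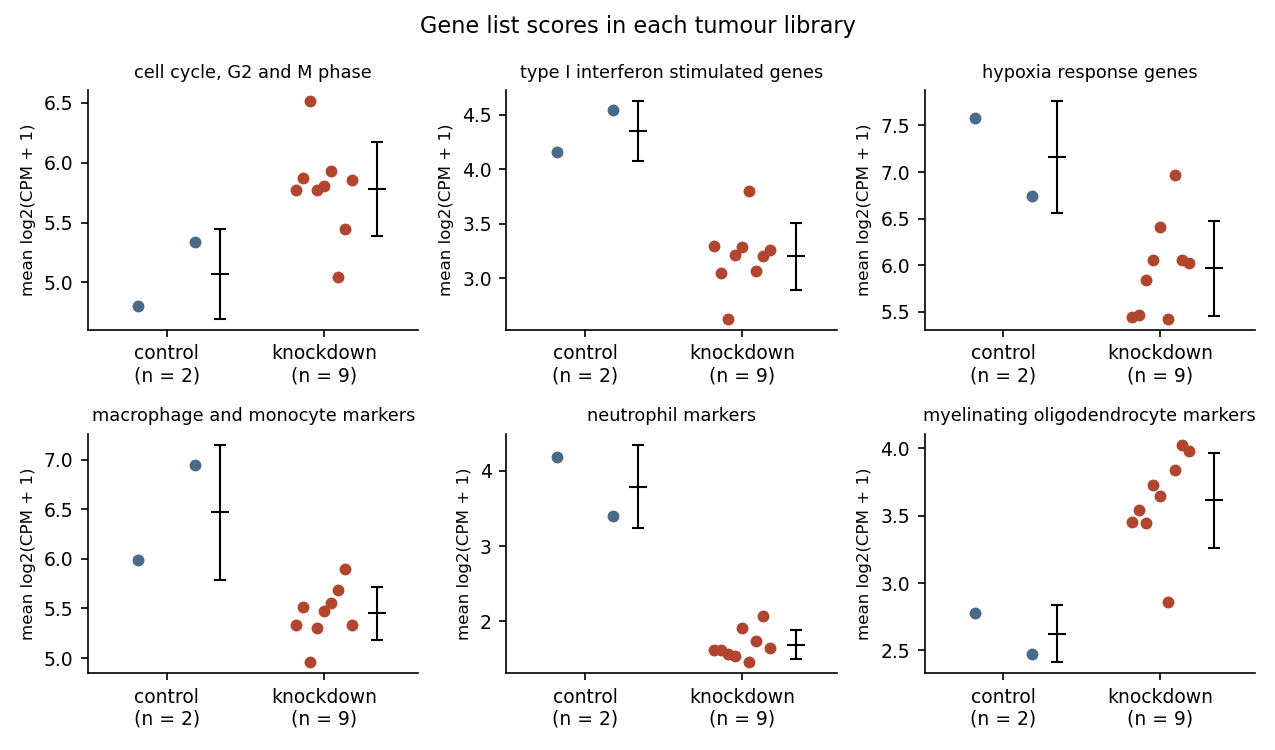
Mean log2(CPM + 1) over the members of 6 gene lists in each control (blue, n = 2) and knockdown (red, n = 9) library, with group mean and SD as black bars; axes do not start at 0. Neutrophil scores lie between 1.46 and 2.07 in the knockdown and at 3.40 and 4.18 in the controls, while G2 and M phase scores of the groups overlap.

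Hypoxia and amino acid stress genes were lower as well. Of 28 hypoxia response genes 17 fell and none rose (median log2 fold change -1.17; camera, adjusted p = 7.0e-06, and adjusted p = 0.68 with an estimated correlation), such as the collagen hydroxylase P4ha2 (4.12-fold, adjusted p = 0.0012) and Stc2 (5.76-fold, adjusted p = 0.0031). Without control 1 the list passed with 1 member falling (median -0.75). Of 28 targets of ATF4, the transcription factor of the integrated stress response, 12 fell (17 adjusted over the list alone) and 2 rose (median -0.66; adjusted p = 5.7e-05, and adjusted p = 0.68 with an estimated correlation). The glutathione-degrading enzyme Chac1 fell 7.71-fold and the cystine transporter Slc7a11 fell 6.71-fold, with control SDs of 20.7 and 112 CPM around means of 21.5 and 117 CPM, whereas Pck2 rose 1.52-fold and Cebpb 1.91-fold. Without control 1 the ATF4 call was lost (0 members, adjusted p = 0.12). No mitochondrially encoded gene passed (0 of 12; list adjusted p = 0.16), the smallest p belonging to mt-Nd3 and mt-Atp8, with log2 fold changes of 1.00 ± 0.53 and 1.07 ± 0.59. Of 40 nuclear-encoded respiratory chain genes 1, Ndufa5, rose 1.75-fold, and of 42 ribosomal protein genes 1, Rps2, fell 1.57-fold; neither passed adjusted over the list alone (list adjusted p = 0.52 and 0.30). Of 22 immediate early genes 4 rose and 3 fell, or 5 and 4 adjusted over the list alone (list adjusted p = 0.86), with Egr3 and Egr2 rising 3.40-fold and 3.09-fold and Klf6 and Jund falling 1.5-fold and 1.63-fold.

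Among markers of neural cells, those of myelinating oligodendrocytes were higher. Of 20, 7 rose and 2 fell (median log2 fold change 1.72; camera, adjusted p = 0.0031, and adjusted p = 0.68 with an estimated correlation). Mbp, myelin basic protein, rose from 17.2 ± 13.3 to 175 ± 53.8 CPM (adjusted p = 0.0015), while Aspa, aspartoacylase, fell 9.98-fold and Gsn, gelsolin, 2.24-fold. In the 7 libraries with Xist reads the myelin list did not pass (adjusted p = 0.069), an alternative chosen after seeing the data, and without control 1 and control 2 its members that rose were 3 and 2. Of 31 neuron markers 4 rose and 1 fell (median 0.86; list adjusted p = 0.42), with Nrgn and Snap25 9.92-fold and 6.24-fold higher and Syn1, whose model overlaps Timp1, 3.74-fold lower. Of 22 oligodendrocyte precursor markers 5 rose (6 adjusted over the list alone) and 2 fell (list adjusted p = 0.88). The proteoglycan Vcan rose 4.55-fold to 803 ± 333 CPM and the lineage factors Olig2 and Olig1 fell 6.53-fold and 5.16-fold. The size of both falls depends on control 2, since Olig2 had 225 counts in control 1 and 721 in control 2, and Olig1 568 and 1522. Neu4 rose too, on 1 count over both controls, with a ratio of summed counts of 40.4 (95% exact binomial interval 7.16 to 1603). Of 26 neural stem and progenitor markers 2 rose and 5 fell, 7 adjusted over the list alone (list adjusted p = 0.24): Egfr and Fut4 rose 1.95-fold and 2.51-fold, and Nes, nestin, and Tnc, tenascin C, fell from 1460 ± 802 to 397 ± 78.1 CPM and from 2058 ± 91.1 to 671 ± 166 CPM. Of 26 astrocyte markers 1, Clu, rose 4.89-fold and 3 fell, including Slc6a11 and Acsl6, the latter 4.21-fold (list adjusted p = 0.69). Of 11 ependymal markers 1, Pltp, whose model overlaps Ctsa, fell 4.90-fold (list median 0.41, camera direction lower, adjusted p = 0.90). Of 8 choroid plexus markers 2 rose, 3 adjusted over the list alone (list adjusted p = 0.52), Folr1 14.2-fold, on 4 counts over both controls, and Enpp2, which oligodendrocytes also make, 7.64-fold.

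Of 34 mesenchymal signature genes 8 fell (12 adjusted over the list alone) and 1, Cebpb, rose (median log2 fold change -0.38; camera, adjusted p = 0.011, and adjusted p = 0.68 with an estimated correlation). The collagen Col1a2 fell from 1154 ± 21.4 to 63.9 ± 50.5 CPM (adjusted p = 0.00082) and Traf3 fell 1.61-fold. This list shares 8 genes with the extracellular matrix list and 3 with the macrophage list, and 3 and 5 of its members fell without control 1 and control 2. Of 22 proneural genes 3 rose and 4 fell, 5 adjusted over the list alone (list adjusted p = 0.53); Pdgfra and P2ry1 rose 2.31-fold and 3.35-fold, and Ncam1 fell 2.29-fold beside Olig2. Of 21 genes of the epithelial to mesenchymal transition 3 rose and 4 fell, or 4 and 6 adjusted over the list alone (median 0.27, camera direction lower, adjusted p = 0.69). The transcription factor Snai1 rose 4.81-fold to 125 ± 22.6 CPM (adjusted p = 0.00021) beside Twist1, while Zeb2 fell 1.76-fold (adjusted p = 0.00028) and Mmp9, gelatinase B, 17.8-fold. Of 41 extracellular matrix genes 6 rose and 8 fell (median 0.14, mean -0.04, camera direction lower, adjusted p = 0.58), with the laminin Lama2 16.1-fold and the proteoglycan Bgn 3.18-fold higher and Sparc and Tnc among those lower. Of 24 endothelial markers 7 rose and 4 fell, or 10 and 5 adjusted over the list alone (list adjusted p = 0.085): Plvap and Ramp2 rose 6.20-fold and 4.72-fold, and the VEGF receptor Flt1 and the lipid transporter Mfsd2a fell 5.32-fold and 1.83-fold. The endothelial list passed, with 13 higher and 2 lower (adjusted p = 0.0061), in the fit without knockdown libraries that had a shifted chromosome, chosen after seeing the data, whereas 1 rose and 1 fell without control 1, and 1 rose and 4 fell without control 2. Pericyte and smooth muscle markers (2 higher and 3 lower of 17, list adjusted p = 0.95) included Pdgfrb, 4.67-fold higher, Abcc9, 2.50-fold higher, and Anpep and Tagln, 2.99-fold and 3.00-fold lower. Of 17 fibroblast and meningeal markers Pdgfra and Islr rose, the latter 4.90-fold, and Col1a2 fell (list adjusted p = 0.95; median 0.47 and camera direction higher, but fry's direction lower). No blood marker passed (0 of 5, list adjusted p = 0.15), with Hbb-b1 at 1.48 ± 0.67 on the log2 scale.

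Of the signalling lists, the one for BMP and TGF-beta was lower. Of its 23 genes 7 fell and none rose (median log2 fold change -0.51; camera, adjusted p = 0.017, and adjusted p = 0.68 with an estimated correlation), with Ltbp1, which binds latent TGF-beta, falling from 754 ± 63.4 to 189 ± 74.8 CPM (adjusted p = 0.0033) and Ltbp2 3.87-fold. Without control 1 the call was lost (2 members, adjusted p = 0.19). Of 19 Notch pathway genes 2 rose and 5 fell (list adjusted p = 0.24), with Notch2 and Hey2 rising 1.52-fold and 3.73-fold and Lfng and Rbpj, the DNA-binding partner of Notch, falling 3.18-fold and 2.64-fold. Of 21 Wnt targets 2 rose and 6 fell (median 0.13, camera direction lower, adjusted p = 0.52), with Tcf7 and Nkd1 3.08-fold and 3.19-fold higher and Sfrp2 and Lgr6 8.81-fold and 5.55-fold lower. Of 11 Hedgehog genes 1, the effector Gli2, rose by 1.85 ± 0.30 on the log2 scale (adjusted p = 0.0016; list adjusted p = 0.083). Of 18 genes that report RAS-MAPK output 1, Spry1, rose 2.55-fold and 3 fell, among them Spred3 and cyclin D1 (Ccnd1), 2.30-fold and 1.98-fold (list adjusted p = 0.58). Of the genes altered in the donor cells, those reported here did not pass: the log2 fold changes were 0.39 ± 0.19 for Cdkn2a, -0.11 ± 0.15 for Trp53 and -0.21 ± 0.17 for Hras, and counts per gene do not tell a recombined allele from an intact one. None of the 5 sex-linked markers passed over all 11 libraries (list adjusted p = 0.32), whereas 4 passed upward in the 7 libraries with Xist reads (edgeR, median 1.35; list adjusted p = 0.094), an alternative chosen after seeing the data. Because those libraries were selected by Xist, itself a member of the list, that fit gives no independent support. Over all libraries the log2 fold changes were -1.29 ± 1.53 for Xist, 1.88 ± 0.73 for Ddx3y, 2.36 ± 0.88 for Uty, 1.97 ± 0.84 for Eif2s3y and 1.66 ± 0.94 for Kdm5d.

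Within the knockdown group, tumours with a higher Ezh2 level had lower macrophage and monocyte scores. Over the 9 libraries Pearson's r between Ezh2 and that score was -0.82 (exact permutation p = 0.0048, adjusted p = 0.039 over 8 relations) and Spearman's rho was -0.73 (exact permutation p = 0.031, adjusted p = 0.12). Without knockdown 3 and knockdown 9, the libraries farthest from the median Ezh2 level, r was -0.75 (exact permutation p = 0.050). Ezh2 and the G2 and M phase score gave r = 0.75 (exact permutation p = 0.015, adjusted p = 0.062) and rho = 0.73 (exact permutation p = 0.031, adjusted p = 0.12), with r = 0.66 without those libraries (exact permutation p = 0.10). The relations of Ezh2 to S phase (r = 0.65, rho = 0.48) and DNA repair (r = 0.64, rho = 0.50) did not pass (adjusted p = 0.11 for r and 0.26 for rho, exact permutation), nor did those to the pluripotency, Hox, other developmental and myelin scores, with r between -0.33 and 0.23 and adjusted p of 0.60 or more. The relations of Ezh2 to the macrophage and the G2 and M phase scores ran against the difference between the groups, since the controls, with more Ezh2, had a mean macrophage score of 6.47 ± 0.68 (SD, n = 2) against 5.45 ± 0.27 (SD, n = 9) in the knockdown and a mean G2 and M phase score of 5.07 ± 0.37 against 5.78 ± 0.39. In the second family, of 9 relations between scores of neurons, myelin and macrophages and those of G2 and M phase, Ezh2 and astrocytes, only the same macrophage relation passed (adjusted p = 0.043, exact permutation). When the 2 libraries farthest from the median macrophage score were left out, knockdown 3 and knockdown 8, its r was -0.62 and it no longer passed (exact permutation p = 0.14, n = 7). In the same family the macrophage and the G2 and M phase scores gave r = -0.81 (exact permutation p = 0.019, adjusted p = 0.070) and rho = -0.45. Whether Ezh2 levels among these tumours follow the knockdown or the mix of cells in each sample was not tested.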

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

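Looked at over the 9 knockdown tumours were 71 quantities (list scores, total counts, mitochondrial share and the named genes). Of these, 3 had a library that lay apart from the other 8 by Dixon's gap test. Chance alone sets apart about 1 in 20, so that 3 of 71 are no more than chance would give. In knockdown 6 the score of myelinating oligodendrocyte markers was the lowest, 2.86 against 3.45 in the next library. In knockdown 9 the score of the epithelial to mesenchymal transition genes was the lowest, 5.14 against 5.59 in the next. In knockdown 5 the score of the immediate early genes was the highest, 6.58 against 5.71 in the next.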

How the results depend on the processing

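The fits on libraries with Xist reads and without knockdown libraries that had a shifted chromosome were chosen only after the result was seen. The direction of the 3790 changed genes, as far as tested, was kept under RLE and upper-quartile factors, both filters, DESeq2, limma-voom and the test against a 1.5-fold change, with 3300 to 4864 genes passing, except that the 1.5-fold test passed 1159 (450 higher, 709 lower), since it asks for a larger change. Ezh2 then stood at -1.59 with an adjusted p of 0.091 (edgeR; range over all alternatives 0.0014 to 0.14). The share of changed genes that were higher was 44.2%, 40.4% and 47.7% under RLE and upper-quartile factors, 39.8% without the filter, 36.3% under limma-voom (1228 higher, 2151 lower), and 30% and 31.9% without control 1 and control 2. Leaving out 1 library at a time gave between 1290 and 4269 changed genes, 387 to 1957 higher and 903 to 2418 lower, log2 fold changes of Ezh2 from -1.76 to -1.48, and 13 to 24 of the 24 named genes past the threshold. The lowest counts came without control 1 (1290 genes, 16 named genes) or control 2 (1750 genes, 13 named genes), where a single control is left and is assumed to vary like the knockdown tumours; 99.8% of the 3790 genes kept their direction in either case, and Ezh2 had an adjusted p of 0.11 and 0.14. Limma-voom called 15 named genes, and those it lost had all risen; the cause was not tested. With an estimated correlation 0 gene lists passed camera, because genes within the lists are correlated (0.86 in G2 and M phase). With a pseudocount of 0.1 the number of relations that passed in the second family was 0; the cause was not tested. Besides the lists that the report names as losing their call, leaving out 1 library brought past the threshold of camera the imprinted (adjusted p = 0.038) and blood (0.043) lists without knockdown 6, endothelial markers without knockdown 3 (0.017), mitochondrially encoded genes without knockdown 9 (0.036), and the Hedgehog list without control 1 (0.034). The mitochondrially encoded list also passed in the libraries with Xist reads (0.031). The libraries with Xist reads gave 4631 changed genes, and the fit without the 3 knockdown libraries that had a shifted chromosome, with both controls kept, gave 4400, with 88.9% and 92.5% of the 3790 genes among them.

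The numbers 1 and 2 occur in both groups, but nothing in the labels pairs these tumours, and the deviations of same-numbered tumours from their group means correlated at -0.14 and 0.017. A fit with the replicate block over those 4 libraries called 734 genes, 336 higher and 398 lower, of which 622 were also called without it. Fewer libraries entered that fit. Of the results for single named genes under any alternative, 509 kept their side of the threshold and 43 did not, and for single lists 856 kept it, 25 lost and 17 gained it, with no reversal among called values. Depth limits genes near the floor of 3 counts in a library, such as the controls' Nrk and Lin28b. In the simulated counts 29.1% of 2-fold changes were recovered. The alternatives written for normalized values (a pseudocount and a filter in the test of changed genes) were not run, since the table holds counts.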

Other observations

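Of the tests below, those on a lower share of tumour cells and on a few regions of a chromosome were chosen only after the result was seen. Some of the smallest p-values belonged to genes outside the rule for naming, chosen here after their values were seen. Cx3cl1, the ligand of the microglial receptor Cx3cr1, fell from 311 ± 22 CPM (SD, n = 2) in the controls to 28.7 ± 7.02 CPM (SD, n = 9) in the knockdown tumours (edgeR, adjusted p = 4.4e-06). Dock8, a guanine nucleotide exchange factor, fell from 131 ± 0.684 to 20.9 ± 3.15 CPM (adjusted p = 4.3e-06), Cd9, a tetraspanin, from 512 ± 68.4 to 72.0 ± 17.4 CPM, and Cd274, the immune checkpoint ligand PD-L1, from 24.5 ± 8.61 to 3.93 ± 0.684 CPM (adjusted p = 4.0e-05). Dmrta2, a developmental transcription factor, rose from 2.01 ± 0.0957 to 16.2 ± 0.923 CPM (adjusted p = 4.4e-06). These 5 genes kept their direction and passed the test without either control, with adjusted p between 4.7e-05 and 0.00074 (edgeR).

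The knockdown tumours differed in sex-linked transcripts. Xist stood between 41.4 and 106 CPM in knockdown 2 to 6, at 74.2 and 131 CPM in the controls, and at 1.10, 0.427, 0.108 and 0.531 CPM in knockdown 1, 7, 8 and 9. The Y-linked Ddx3y was detected in every library, from 11.8 CPM in control 1 to 131 CPM in knockdown 9, so that the 7 libraries with over 1.5 CPM of Xist held transcripts of both kinds. Donor cells and host tissue are both mouse, and the labels give the sex of neither.

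The count of changed genes was set against the other ways to divide the libraries into 9 and 2. Only 1 of the 55 splits, the real one, gave 3790 genes or more, and the highest of the others gave 136. That is the smallest share 55 splits can give (permutation p = 0.018). Every other split places at least 1 control among the 9, where the group difference widens the spread and lowers the count. A chance division is thus unlikely by this count but cannot be excluded.

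Most interferon-stimulated genes were lower in the knockdown tumours (median log2 fold change -1.34), although the list did not pass camera with an estimated correlation. A single control library does not account for this, since the median without either control was -1.12 or lower. A smaller share of leukocytes may account for it, which cannot be told apart here: 24 pan-leukocyte markers written down before this test, all above 1 CPM in the controls and in none of the other lists, had a median of -1.32, with 18 lower by edgeR's test, and this median minus that of the interferon genes was 0.03 ± 0.22 (bootstrap SE). The most abundant of them, Laptm5, Lcp1 and Lsp1, went from 249 to 64.8, from 245 to 62.9 and from 181 to 62.2 CPM. The lower Ezh2 level itself, the biological explanation that the design names, stays open and untested beside doxycycline.

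Part of the myelin genes were higher in the knockdown tumours (list median 1.72), while Aspa and Gsn were lower. The list did not pass camera with an estimated correlation or in the libraries with Xist reads. A lower share of tumour cells, raising every other cell type alike, would raise microglia markers as much. Their median minus that of myelin was -2.26 ± 0.42 (bootstrap SE over genes, log2). This speaks only against an equal rise. The SE leaves out the spread between tumours, and the test was chosen with the result seen. A lower share of tumour cells with an unequal change of other cells stays open. More surrounding brain in the knockdown samples remains a possible explanation and cannot be told apart. Over the 9 knockdown tumours the myelin and neuron scores rose together (r = 0.82, exact permutation p = 0.0034; rho = 0.75, exact permutation p = 0.025; r = 0.68 without knockdown 6 and knockdown 8, exact permutation p = 0.11, n = 7). The median of the neuron markers minus that of myelin was -0.86 ± 0.60 (bootstrap SE), too imprecise to decide. An effect of Ezh2 knockdown on myelin genes in the tumour cells stays open as well.

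Whole chromosomes were shifted in single tumours. Relative to the median of the other libraries, the median log2 deviation of a chromosome passed 0.2 in 5 of 220 pairs of library and chromosome: chromosome 15 in knockdown 8 (-0.28) and knockdown 9 (-0.37), chromosome 7 (-0.24) and chromosome 13 (0.27) in knockdown 3, and chromosome 4 in control 1 (-0.22), against at most 0.18 in the other pairs. In a permutation test, random gene sets of the same size did not reach these values in 10000 draws (permutation p = 1e-04, the smallest they can give; Bonferroni-adjusted p = 0.022). A few regions are argued against, since 100% of the 20 Mb windows moved with their chromosome. A gain or loss of the chromosome in the tumour cells may account for the shifts, but no DNA was measured here. Genes above and below median expression moved the same way by at least 0.157. The pairs had been picked for a median beyond 0.2 over the same genes, so this does not tell a gain or loss from another cause. No biological explanation from the design was tested.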
